A study of Drosophila melanogaster with 4 samples.

How the data were processed

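Whole embryos of *Drosophila melanogaster* were compared on 4 two-colour Agilent oligonucleotide arrays, each of which carried RNA from homozygous mir-3 ectopic expression embryos in one dye and RNA from wild-type w1118 embryos in the other. Per the labels, eggs were collected for 2 h at 25 °C and aged to 6 to 8 h after laying, and total RNA was purified, checked on a Bioanalyzer, amplified and labelled with an Agilent kit. The labels name 3 biological replicates per genotype, isolated separately, and a dye swap of replicate 1. The mir-3 ectopic RNA carried Cy3 on 3 arrays and Cy5 on the dye-swap array.

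Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.1.1.1. The deposited scanner files hold spot intensity as median foreground and median local background signals on a linear scale, with flags for non-uniform, population-outlier, saturated and well-above-background spots. They also hold the processed signals of Feature Extraction and, per the file headers, log10 ratios of Cy5 over Cy3 from the authors' scanner software, which served only to check the value table. The authors' value table holds log2 ratios per probe. Set against the scanner files, each column equalled log2 of the processed Cy5 signal over the processed Cy3 signal within 2.67e-06 to 3.54e-06, with the sign turned on the dye-swap array. Its scale and direction are thus known, and it was not centred on its median, the column medians being -0.11, -0.07, 0.11 and -0.15 for replicates 1, 2 and 3 and the dye swap. By the labelled dyes that table is wild type over mir-3 ectopic. Every ratio given here is the other way round, log2 of mir-3 ectopic over wild type.

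The analysis had been planned on mean foreground signals. The scanner files used here give median ones, so background was corrected from the median signals with normexp (offset 50) in limma 3.58.1 under R 4.3.3 with statmod 1.5.0. Ratios were normalized within each array by loess with control spots at weight 0. Control spots and spots with outlier flags were then left out (107, 121, 173 and 157 flagged spots on replicates 1, 2 and 3 and the dye swap), and spots of the same probe were averaged. A probe was kept if it was well above background in the channel of at least 1 genotype on at least 3 of the 4 arrays, which kept 19734 of 32162 distinct probes. The log2 ratios of a gene's kept probes were averaged. Of 3361 genes with at least 2 kept probes, 178 had probes called in opposite directions, and such a gene is named as uncertain. The identifiers of 19620 probes were matched to gene symbols in a RefSeq gene table (assembly Release 6 plus ISO1 MT), 18121 by locus tag, 1248 by older locus tag, 136 by synonym and 115 by accession. Another 11589 probes carried other identifiers, 521 a CG number and 432 an accession that the table did not hold, and these kept the name in the file. The files name an older build, BDGP5.4, so the table served for names and gene order alone and no coordinates are printed. A genome sequence was not used here.

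Arrays were turned the same way by the labelled dyes, the 2 arrays of replicate 1 were averaged, and the 3 replicate ratios were tested against 0 with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment over the 14857 genes and unnamed transcripts tested and a threshold of 0.05. Because a gene's ratio comes from paired channels, the spread is that between replicate pairs. Dye effects cancel within replicate 1 but not within replicates 2 and 3, so a fit of the 4 arrays with the dye as a term is given beside the main counts. In that fit the dye-swap array is fitted exactly, and the spread comes from the 3 arrays of the other orientation. Tested on simulated data for this comparison with 14857 genes, the 3-replicate test recovered 26% of 50 genes changed by 0.25 on the log2 scale, 74% of 50 changed by 0.5, 98% of 50 changed by 1 and 100% of 50 changed by 2, and called 7 unchanged genes. With a simulated dye effect of SD 0.3 it called 1 unchanged gene and the dye-term fit 4. That effect was larger than the measured one, of median absolute size 0.067. The simulation changed 200 genes, where 7247 were called in these data. Its counts of unchanged genes called may therefore not hold here, and they do not address dye bias of the measured size.

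Gene lists were compared with the other genes by camera with a preset inter-gene correlation of 0.01 and by camera with an estimated correlation. The estimated form tests on the few residual degrees of freedom that 3 replicates leave, so a list can hardly pass it after adjustment. A miss there does not show that correlation between genes accounts for a list, and the calls rest on the preset value. Each list was also tested against no change by fry, which makes no comparison with other genes. All were adjusted over 23 lists. The lists were mesoderm and muscle regulators, cardiac and pericardial genes, myoblast fusion and founder cell genes, sarcomere and contractile genes, maternal transcripts cleared early, early zygotic patterning genes, late embryonic cuticle and chitin genes, nervous system genes, Notch and E(spl) genes, endoderm and gut genes, hemocyte and basement membrane genes, trachea and salivary gland genes, germ cell genes, antimicrobial and immune genes, heat shock and stress genes, cell death genes, cell cycle and DNA replication genes, miRNA pathway genes, ribosomal proteins, histones (drawn up as replication-dependent histones, though the measured members were variant or replacement histones), yolk and female reproductive genes, larval and adult tissue genes and reference housekeeping genes. Genes were named by a rule: *Mef2* and *tin* always, *w* as a check of direction, the 12 largest positive and 12 largest negative ratios among genes past the threshold with the same sign on all 4 arrays and a symbol or CG number, and up to 4 members with the smallest p from each list. Other members are named where a count needed them, and those were chosen after their values were seen. The groups, the fit, the lists, the rule for named genes and the alternatives were set before the data were examined, apart from the median-centred version of the value table and the glycolysis list and gene families of the closing part.

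Alternatives changed the background correction, the normalization within and between arrays, the filter on dim probes, the rule for several probes per gene, the treatment of the dye and of the dye-swap array, the pairing of channels, the eBayes settings, the slide as a random block, the fold threshold and the replicates used, and took the authors' processed signals or value table in place of the scanner signals. A planned test of transcripts with miR-3 seed matches in their 3′ UTRs was not run, because UTR sequences were not used here.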

Results

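RNA from embryos with ectopic expression of mir-3, a microRNA, was hybridized against RNA from wild-type w1118 embryos of the same age, 6 to 8 h after egg laying, in 3 biological replicates on 4 arrays, the fourth array being a dye swap of replicate 1. Each array carried 45020 spots. Median Cy3 signals were 81, 63, 71 and 95 for replicates 1, 2 and 3 and the dye swap, against median backgrounds of 25, 20.5, 20 and 26, and median Cy5 signals were 152.5, 146, 110 and 150.5 against 53, 47.5, 46.5 and 53. Between 57.6% and 64.7% of spots were well above background in the mir-3 ectopic channel and between 59.1% and 66.1% in the wild-type channel, with 0 saturated spots. The number of arrays limits the precision. Across 14855 genes, which are not independent replicates, the log2 ratios of the 3 arrays of the same dye orientation correlated with Pearson's r of 0.941 to 0.945 and Spearman's rho of 0.884 to 0.891, and those of the dye-swap array with the other arrays less closely, at r of 0.752 to 0.800 and rho of 0.535 to 0.591.

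The series title names *Mef2* and *tin*, and the comparison asked how their transcripts and others differed with mir-3 ectopically expressed. The transcript of *tin* (CG7895), the homeobox gene of heart and dorsal mesoderm, was lower in mir-3 ectopic embryos, with a log2 ratio of -0.73 ± 0.15 (SD, n = 3), or 1.66-fold lower. *Mef2* (CG1429), the MADS-box regulator of muscle differentiation, was higher by 0.16 ± 0.03 (SD, n = 3), or 1.12-fold. These directions, and every increase or decrease given below, rest on the labelled dyes and are opposite to the sign of the authors' value table; were the labelled dyes reversed, each increase would be a decrease of the same size and each decrease an increase. The limma adjusted p (Benjamini-Hochberg) was 0.00013 for *tin*, with SE 0.06, and 0.018 for *Mef2*, with SE 0.04, and each had the same sign on 4 of 4 arrays. The *tin* ratio came from 1 probe and was -0.64 on the array of replicate 1, -0.79 on its dye swap, -0.58 in replicate 2 and -0.89 in replicate 3. The 5 kept *Mef2* probes ran from -0.11 ± 0.08 to 0.41 ± 0.12 (SD, n = 3), and the *Mef2* call was lost without replicate 2 (limma adjusted p 0.062), without replicate 3 (0.11), with the dye-swap array alone for replicate 1 (0.070), with unpaired channels (0.19) and, like that of *tin* (0.44), with median centring in place of loess (1.0), at *Mef2* ratios of 0.15 to 0.18 in these settings and a *tin* ratio of -0.76. The *Mef2* ratio was 0.29 with the processed signals and 0.41 for its brightest probe, but the next brightest probe (mean log2 signal 13.34 against 13.57), named for the same transcript, was at -0.11 and did not pass (limma adjusted p 0.11). The remaining *Mef2* probes were far dimmer, at mean log2 signals of 7.18, 6.89 and 7.69 and ratios of 0.11, 0.17 and 0.23. The SD of 0.03 for *Mef2* is that of the ratio averaged over probes and leaves out this disagreement. No kept probe was named for mir-3, so its own level was not analysed here. The gene *w* (CG2759), carried by many transgenes as an eye-colour marker and named as a check of direction, would be higher in mir-3 ectopic embryos if their stock carried such a marker, which is not given in the sources used here. It had a ratio of -0.11 ± 0.06 (SD, n = 3) that did not pass (limma adjusted p 0.088), and it passed as lower with the dye as a term (-0.17, limma adjusted p 0.0064) and for its brightest probe (-0.17, 0.024). That sign is opposite to what such a marker would give by the labelled dyes, and the direction was not settled by it.

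**Figure D1:**
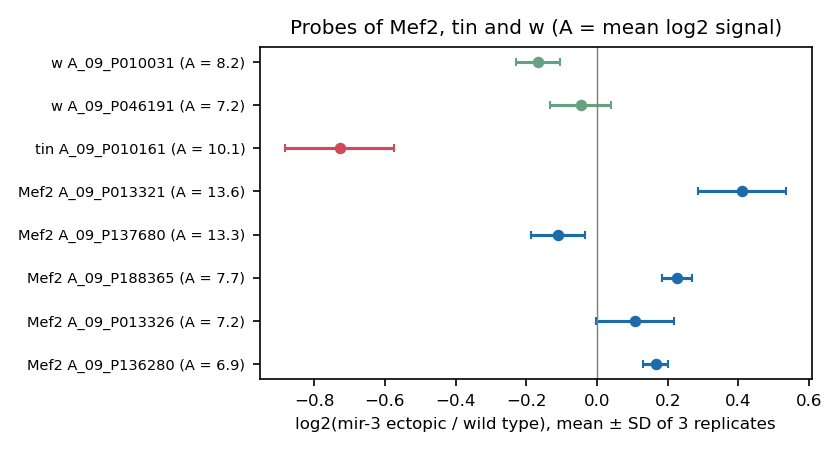
Log2 ratio of mir-3 ectopic over wild type for each kept probe of *Mef2*, *tin* and *w*, as points with bars for the SD of 3 replicates; A is the mean log2 signal of the probe. The *tin* probe lies at -0.73, the *Mef2* probes between -0.11 and 0.41, and the *w* probes at -0.17 and -0.05.

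Over the whole array, 3612 genes and unnamed transcripts were higher and 3635 lower in mir-3 ectopic embryos by limma with Benjamini-Hochberg adjustment, and 7610 did not pass. Most of these differences were small, with a median absolute log2 ratio of 0.27 among those called, against a median SD between replicates of 0.07. At least 2-fold changes were called for 84 higher and 167 lower, and with the Feature Extraction processed signals for 287 and 594. Of the 7247 calls, 6324 had the same sign on all 4 arrays. Without replicate 2 the counts were 2732 higher and 2402 lower, and without replicate 3 they were 2520 and 2221. With the dye as a term of the fit 3990 were higher and 4079 lower, and 6450 of the 7247 calls kept their sign and passed. Median centring in place of loess left 24 higher and 58 lower, and unpaired channels 2370 and 2071. The 4 arrays lay on 2 slides, replicate 1 on the first and replicates 2 and 3 on the other: the slide as a random block gave 3375 higher and 3206 lower, replicates 2 and 3 alone 4008 and 4243, and the slide of replicate 1 holds too few replicates for a test. With the block, the dye swap entered as a separate array, at a correlation within slide of -0.05. Taking the 4 arrays as 4 replicates gave 3297 and 3121. Slide and replicate cannot be told apart here, so the block does not settle a slide effect.

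The largest increase was that of CG4408, at 3.66 ± 0.30 (SD, n = 3), or 12.6-fold, with wild-type signal well above background on 3 of 4 arrays. CG11825 followed at 3.06 ± 0.16 and CG11034 at 2.82 ± 0.15 (SD, n = 3). Among the others, *eIF4E3*, an eIF4E-family cap-binding protein, rose by 2.75 with its 3 probes between 2.53 and 2.89, *Tektin-C*, a protein of ciliary and flagellar microtubules, by 2.50, and *corolla*, a synaptonemal complex protein, by 2.04. *Scp1*, a sarcoplasmic calcium-binding protein, rose by 2.72, CR14033 by 2.43, the nucleotidase *cN-IIIB* by 2.34, the acyl-CoA dehydrogenase *Acadvl* by 2.19, CG14692 by 2.14 and the glutathione S-transferase *GstE11* by 1.90. Among these 12 the replicate SD ran from 0.03 for *cN-IIIB* to 0.30 for CG4408, and the limma adjusted p was at most 4.5e-06 (*Acadvl*). With the processed signals, which replace both the background correction and the normalization, CG4408 was at 6.06, *eIF4E3* at 4.47 and CG14692 at 3.57, and with no background subtraction alone they were at 4.19, 3.22 and 2.49.

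The serpin gene *Spn28Da* showed by far the largest decrease, at -7.39 ± 0.11 (SD, n = 3), or 168-fold, on 2 probes at -7.38 and -7.41. Of the 12 genes, 6 encode cuticle proteins: *TwdlD* (-3.71), *TwdlW* (-3.31), *TwdlL* (-2.90) and *TwdlK* (-2.64), all of the Tweedle family, *Lcp65Ag2* (-3.09) and *Cpr51A* (-3.01). *Lcp65Ag2* has near-identical copies that its probes may also bind, and is uncertain to that extent. Lower too were CG2962 (-3.71), *Cpn* (-3.69), which encodes the photoreceptor calcium-binding protein calphotin, *dhd* (-3.26), a thioredoxin of the female germline, the glycolytic *Gapdh2* (-2.96) and *Dnaaf3* (-2.95), a dynein arm assembly factor. Mutant signal was well above background on 3 of 4 arrays for *TwdlD*, *TwdlW* and *Cpr51A* and on 1 of 4 for *Cpn*. The limma adjusted p was at most 1.2e-06 (*TwdlK*). With the processed signals *Cpn* was at -6.91, *TwdlW* at -6.07, *TwdlD* at -5.94, *TwdlL* at -5.15 and *Cpr51A* at -4.94, and with no filter on dim probes CG2962 was at -1.96.

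**Figure D2:**
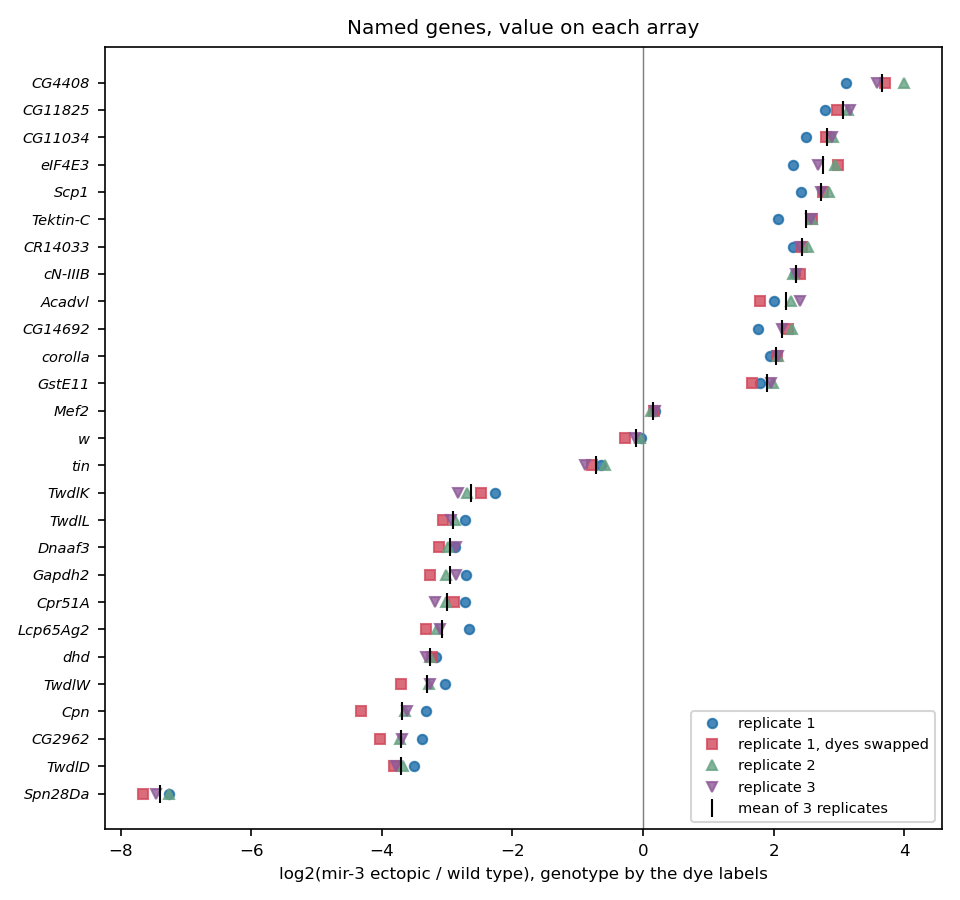
Log2 ratio of mir-3 ectopic over wild type on each of the 4 arrays for *Mef2*, *tin*, *w* and the 12 genes with the largest increase and the 12 with the largest decrease; the tick marks the mean of 3 replicates. *Spn28Da* lies at -7.39, apart from the other genes, which run from -3.71 to 3.66.

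Genes of cuticle and muscle structure fell with the preset correlation, and the lists of mesoderm and heart regulators did not pass. Of 34 measured genes of late embryonic cuticle and chitin, 26 fell, 1 rose (*Muc11A*, 0.54) and 7 did not pass, with a median of -0.35 (camera adjusted p 2.7e-09, but adjusted p = 0.51 with an estimated correlation) and medians of -0.31, -0.41 and -0.46 in replicates 1, 2 and 3. Adjusted over the list alone, 26 were lower and 1 higher. *TwdlL*, *TwdlG* (-2.56), *TwdlM* (-2.18) and *Osi15* (-2.08) had the smallest p. Of 30 sarcomere and contractile genes, 17 fell, 1 rose (*flw*, a myosin phosphatase subunit, 0.38) and 12 did not pass, with a median of -0.20 (camera adjusted p 2.6e-05, but adjusted p = 0.51 with an estimated correlation) and medians of -0.19, -0.23 and -0.18 in the 3 replicates. Adjusted over the list alone, 17 were lower and 1 higher. The troponin I gene *wupA* was at -1.25, the myosin heavy chain *Mhc* at -1.42, paramyosin *Prm* at -1.21 and the myosin light chain *Mlc1* at -1.43. The tropomyosin gene *Tm1* is uncertain, its probes being called in both directions, from -0.96 to 0.44. With the processed signals the medians were -0.86 for the cuticle list and -0.36 for the sarcomere list, and without background subtraction or without the filter on dim probes the cuticle median was -0.54 or -0.16.

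Among 29 cardiac and pericardial genes 11 fell, 3 rose and 15 did not pass (camera adjusted p 0.27), with the same counts of 11 and 3 adjusted over the list alone. After *tin*, the T-box genes *Doc1* (-0.41) and *Doc3* (-0.40) and the pericardial matrix gene *prc* (-0.37) had the smallest p. Among 35 mesoderm and muscle regulators 9 fell, 4 rose and 22 did not pass (camera adjusted p 0.47), again 9 and 4 adjusted over the list alone. The zinc finger gene *Kr* rose by 1.48, and the Hox gene *Ubx* (-0.26) and *Him* (-0.20) fell, with *tin*. Of 26 myoblast fusion and founder cell genes 6 fell, 4 rose and 16 did not pass (camera adjusted p 0.98), the same adjusted over the list alone, among them the GTPases *Rac1* (0.31) and *Rac2* (-0.43), whose sequences are near-identical in places.

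Of 24 miRNA pathway genes, 12 rose, 3 fell and 9 did not pass, with a median of 0.17 (camera adjusted p 0.025, but adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 15 were higher and 3 lower. The call of this list was lost with the processed signals at a median of 0.18 (camera adjusted p 0.089). The deadenylase scaffold *Not1* rose by 1.53, *smg*, a repressor of maternal mRNAs, by 0.71, the small RNA methyltransferase *Hen1* by 0.83 and the Drosha partner *pasha* by 0.48. Of 23 Notch and E(spl) genes 11 fell, 1 rose and 11 did not pass, with a median of -0.14 (camera adjusted p 0.020, but adjusted p = 0.51 with an estimated correlation), and adjusted over the list alone 13 were lower and 1 higher. With median centring in place of loess the list did not pass at a median of -0.17 (camera adjusted p 0.25). The riser was *Su(H)* (0.73), the transcription factor of the pathway, and *BobA* (-0.37), *E(spl)mgamma-HLH* (-0.42) and *Tom* (-0.33) fell. Of 80 ribosomal protein genes 37 fell, 3 rose and 40 did not pass, with a median of -0.12 (camera adjusted p 0.00018, but adjusted p = 0.63 with an estimated correlation), the same counts adjusted over the list alone. The median of this list was 0.05 on the dye-swap array. With the dye as a term 26 were lower and 4 higher, and the list still passed at a smaller median of -0.05 (camera adjusted p 0.026). With the processed signals the list did not pass (median -0.03, camera adjusted p 0.54). *RpS21* fell by 0.96, *RpL8* by 0.69, *RpL38* by 0.33 and *RpL31* by 0.39.

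Among markers of other tissues, the hemocyte and nervous system lists were lower with the preset correlation by narrow calls that many alternatives lost. Of 23 hemocyte and basement membrane genes 9 fell and 2 rose (camera adjusted p 0.043, but adjusted p = 0.51 with an estimated correlation), the matrix genes *Tig* (-0.71) and *Glt* (-0.67), the peroxidase *Pxt* (-0.57) and the prophenoloxidase *PPO1* (-0.57) among them. Of 56 nervous system genes 16 fell and 3 rose (camera adjusted p 0.043, but adjusted p = 0.63 with an estimated correlation), with the proneural genes *l(1)sc* (-0.58), *ac* (-0.38) and *ato* (-0.27) lower and the neuronal RNA-binding gene *Rbp9* (0.31) higher. With the dye as a term neither list passed: the nervous system median went from -0.07 to -0.04 (camera adjusted p 0.16), being 0.0013 on the dye-swap array, and the hemocyte median from -0.05 to -0.08 (camera adjusted p 0.057). Of 18 alternatives 11 lost the nervous system call, among them leaving out replicate 2 (camera adjusted p 0.15) or replicate 3 (0.060), and 8 lost the hemocyte call, among them leaving out replicate 1 (0.091), 2 (0.066) or 3 (0.051), with medians from -0.07 to -0.05 in these. Of 25 trachea and salivary gland genes 9 fell and 3 rose (camera adjusted p 0.24), *PH4alphaSG2* (-0.54) and *pnt* (0.37) among them. In each of these 3 lists the counts were the same adjusted over the list alone. Of 36 endoderm and gut genes 5 rose and 7 fell (camera adjusted p 0.98), and adjusted over the list alone 5 and 6, with *Kr*, the maltase *Mal-A1* (1.02) and the amylase *Amy-p* (0.77) higher.

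Germline and maternal transcripts went both ways. Of 29 germ cell genes 11 rose and 9 fell (camera adjusted p 0.42), the same adjusted over the list alone, with *eIF4E3* and the gap junction gene *zpg* (1.68) higher and *pgc* (-1.76) and *osk* (-1.21) lower. Of 37 maternal transcripts cleared early 14 rose and 12 fell (camera adjusted p 0.98), and adjusted over the list alone 15 and 14. The maternal tubulin *alphaTub67C* fell by 2.56, *nanos* by 1.44, *osk* by 1.21 and *mtrm* by 0.99. Of 38 early zygotic patterning genes 6 rose and 8 fell (camera adjusted p 0.54), and adjusted over the list alone 6 and 7, with the cellularization genes *slam* (0.80) and *Sry-alpha* (0.53) higher and *btd* (-0.63) lower.

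Of 43 cell cycle and DNA replication genes 18 rose and 8 fell (camera adjusted p 0.16), and adjusted over the list alone 18 and 9, with the securin *pim* (1.05), *Orc1* (1.01), *CycB3* (0.53) and *Cdc6* (0.58) higher. Of 41 heat shock and stress genes 16 rose and 13 fell (camera adjusted p 0.98), the same adjusted over the list alone, with *GstD1* (-1.25), *GstD2* (-1.18), *Hsp26* (-1.18) and *Hsp27* (-0.89) lower. Next by p was *Hsp22*, which was higher (1.16), as was *Hsp23* (0.37). Of 21 cell death genes 4 rose and 10 fell (camera adjusted p 0.23), and adjusted over the list alone 5 and 10, with the caspases *Damm* (-0.75) lower and *Strica* (0.59) and *Dronc* (0.54) higher. Of 19 antimicrobial and immune genes 6 rose and 4 fell (camera adjusted p 0.47), the same adjusted over the list alone, with *Tep2* (-2.16) lower and *cact* (0.57) higher. Of 19 reference housekeeping genes 3 rose and 8 fell (camera adjusted p 0.27), the same adjusted over the list alone, with *Gapdh2* and *Gapdh1* (-1.07) lower and *Cam* (0.47) and *Polr2A* (0.34) higher, *Cam* being uncertain because its probes were called in both directions, from -0.26 to 0.87. Of 12 yolk and female reproductive genes 2 rose and 2 fell (camera adjusted p 0.98), of 11 larval and adult tissue genes 2 rose and 2 fell (camera adjusted p 0.76) and of 5 histone genes, all variant or replacement histones, 1 fell and 0 rose (camera adjusted p 0.47), with the same counts adjusted over the list alone. In these lists the yolk protein receptor gene *yl* was at -1.17, the phospholipase C gene *norpA* at 0.46 and *His4r* at -0.30. No list passed 0.05 after adjustment over the 23 lists in camera with an estimated correlation. That form had few residual degrees of freedom, so its misses carry little weight. The Notch and E(spl) list had a negative estimated correlation (-0.043). Its unadjusted camera p still went from 0.0034 with the preset correlation to 0.084. By fry, which tests a list against no change and not against other genes, 15 of the 23 lists passed, but the ribosomal protein and nervous system lists, lower by camera with the preset correlation, did not (fry adjusted p 0.0595 for each). Of the 338 called list members, 334 kept their sign under every scaling tried, the exceptions being *RpL15*, *RpL19*, *RpL23A* and *spn-F*.

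**Figure D3:**
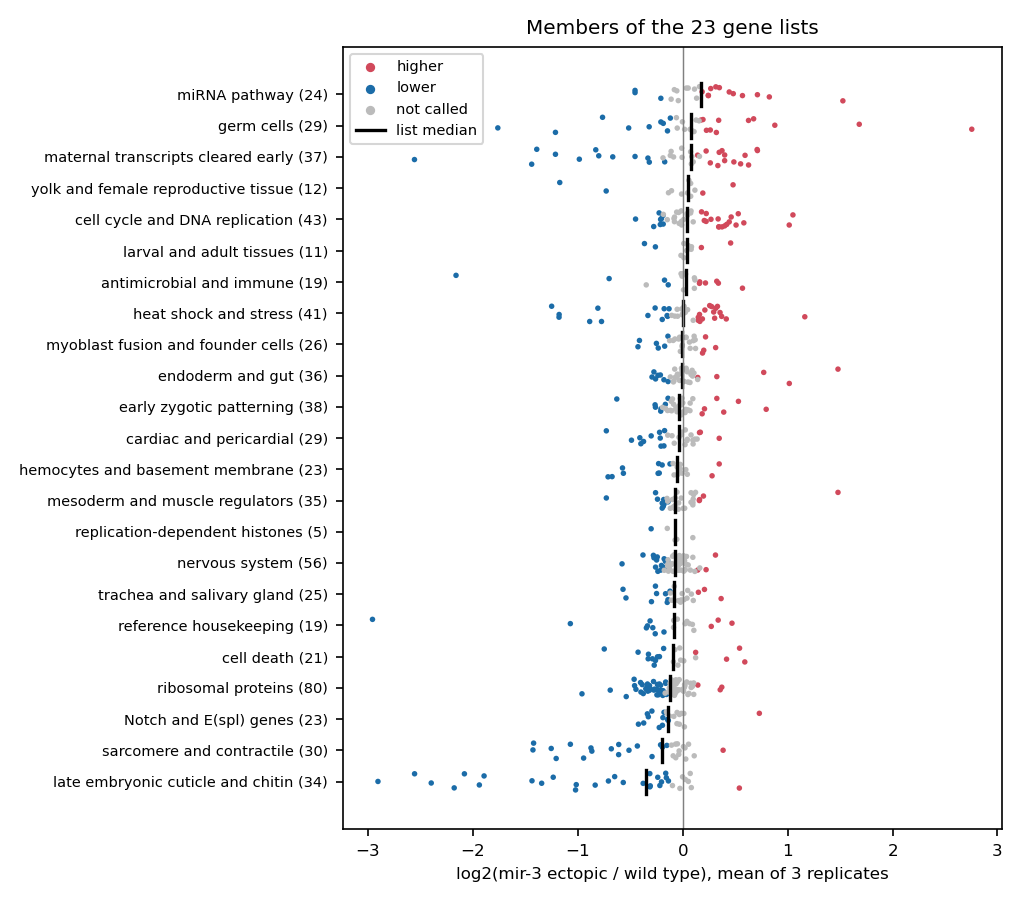
Log2 ratio of mir-3 ectopic over wild type (mean of 3 replicates) for each measured member of the 23 gene lists, with called members coloured by direction, uncalled ones in grey, the list median as a black bar and the number measured in brackets. The cuticle and sarcomere medians, -0.35 and -0.20, are the lowest.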

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

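The test of sign patterns below was chosen only after the result was seen, and the other tests were set out once the largest single-gene ratios had been seen but before their own results were. Of 50 sets of 4 arrays examined for an array standing apart from the rest, 4 had one, where chance gives about 1 in 20 sets. *Tektin-C* was at 2.06 on the array of replicate 1 and between 2.57 and 2.59 on the other arrays. *corolla* was at 1.945 there and between 2.055 and 2.065 on the others. The median of the heat shock and stress list was -0.095 on the dye-swap array and between 0.035 and 0.051 on the others. The median of the ribosomal protein list was 0.055 on the dye-swap array and between -0.181 and -0.156 on the others.

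The number of genes called, 7247 with 3 replicates, was set against chance and dye bias. Of the 4 sign patterns of the 3 replicate ratios, 1 gave as many calls, the real one; the highest of the others gave 0 by limma after adjustment and 54 at an unadjusted p under 0.05, and 4 patterns are too few for a share under 0.05. Dye bias left in replicates 2 and 3 was argued against as the whole source, since 89.002% of the calls kept their sign and passed with the dye as a term, where at least 80% had been set as the bound. That fit matches the dye-swap array exactly, so the error of that array is not in its spread. The share kept therefore does not clear single calls of dye bias. A dye effect was nonetheless called for 2441 genes. Across genes, the difference of replicates 2 and 3 from replicate 1 followed it (Pearson's r -0.70). Both are computed from the 1 dye-swap array, so noise in that array would give a negative r too, and r does not tell the 2 apart. With that array alone for replicate 1 only 4323 of the 7247 calls kept their sign and passed. Dye bias stays open for single calls, also those kept with the dye as a term, and for the ribosomal protein and nervous system lists. No biological explanation was tested.

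The lower cuticle genes were set against a difference in embryo age and a general loss of late tissue markers. If the mir-3 ectopic embryos were younger, the maternal and early zygotic medians were predicted to lie above 0 in every replicate. Both medians below 0.1 in every replicate had been set as the opposite outcome. The early zygotic median was -0.031 (95% bootstrap interval over list members -0.106 to 0.0027), and -0.016, -0.076 and -0.012 in replicates 1, 2 and 3. The maternal median was 0.075 (-0.17 to 0.22), and 0.019, 0.031 and 0.062 in the replicates. It was 0.017 with the dye as a term and 0.013 with the processed signals. The replicate medians thus lay below 0.1, the outcome set against a younger age. Those of the maternal list were nonetheless above 0 in every replicate, as a younger age predicted, and those of the early zygotic list were not. The bootstrap intervals were not part of the prediction. By the width of the maternal interval a younger age was still left open, and whether these lists respond to age at 6 to 8 h was not tested. The nervous system median was -0.075 (-0.131 to -0.034) against -0.20 for sarcomere and -0.35 for cuticle genes, but it was -0.04 with the dye as a term and 0.0013 on the dye-swap array, so a general loss of late markers and a loss of cuticle and muscle transcripts cannot be told apart. An effect of mir-3 itself stays open and was not tested separately.

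The single genes with very large ratios were set against probes that match only one strain and against linked chromosome segments that differ between the stocks. A mismatched probe would leave the probes of a gene apart; the test was planned on the named genes, where 4 of 4 with at least 2 kept probes had every probe past 50% of the gene's ratio, and over all genes past 1 on the log2 scale it held for 37 of 48 (77.1%), which leaves mismatch open, also because most of the 196 genes have 1 probe. Neighbours sharing the start of their symbol were left out of the count, apart from genes with a CG or CR number. Among the rest, genes past 1 lay next to each other in 11 pairs, where 10000 random draws gave a median of 4 and a 95th percentile of 7 (permutation p = 0.0017), as linked segments would give. Co-regulated neighbours would give this too, *TwdlD* and *Tb* being both Tweedle genes, and pairs of opposite sign were not in clear excess (4 against a median of 2, permutation p = 0.089). Other pairs held genes named above. On the same side were *Prx6c* and CG11825 (1.16 and 3.06), *dpr15* and *Cpn* (-1.47 and -3.69), and *RpS10a* and *Mlc1* (-1.16 and -1.43). The mir-3 ectopic signal of *dpr15* was not well above background on any array, so its decrease is only a bound, at least 2.58-fold. On opposite sides were *Dnaaf3* and *GstE11* (-2.95 and 1.90) and *Kr* and CG30428 (1.48 and -1.15). Linkage was not tested for single pairs. A difference between stocks may thus contribute to these ratios, as a hypothesis, beside an effect of mir-3.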

How the results depend on the processing

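The median-centred version of the authors' value table was chosen after the data were seen. *Mef2*, *tin*, the 24 genes of largest change and the lists past the threshold kept their direction under every alternative run, while medians of the heat shock, fusion, gut, immune and maternal lists, none past the threshold, changed sign under some. Counts of 3612 higher and 3635 lower genes moved by over 1.5 times with median centring in place of loess (24 and 58), replicate 1 from the dye-swap array only (2229 and 2094), unpaired channels, that is no replicate block (2370 and 2071), and a fold limit of 1 on the log2 scale (84 and 167). Leaving out a replicate gave 2520 to 4008 higher and 2221 to 4243 lower, the lowest without replicate 3. Without replicate 2 they were 2732 and 2402. The count of lower genes, but not that of higher ones, thus also moved by over 1.5 times without replicate 2 or 3. *Mef2* missed the threshold at a log2 ratio of 0.15 with median centring, 0.16 with the dye-swap array alone for replicate 1 and 0.16 with no replicate block. Leaving out a replicate gave *Mef2* log2 ratios of 0.15 to 0.18, and it missed the threshold without replicate 2 or 3. Of the alternatives run, *tin* missed it with median centring alone, at a log2 ratio of -0.76. The cause was not tested. With the processed signals, which change background correction and normalization together, 2-fold calls were 287 and 594 in place of 84 and 167 (273 and 603 with the median-centred value table, 101 and 239 without background subtraction). Without the block the cuticle and sarcomere lists still passed in camera. Of list results under the alternatives, 387 were on the same side of the threshold, 26 lost it and 1 gained it, the losses falling on the hemocyte, nervous system, ribosomal protein, miRNA pathway and Notch lists. Of single genes 500 were the same, 6 lost it (*Mef2* and *tin*, above) and 2, both *w*, gained it, as lower, at -0.17 with the dye as a term and -0.17 for its brightest probe; its other alternatives, from -0.15 to -0.06, did not pass. The dye-term fit was run without the planned block, the slide block on 4 arrays (no list test), and the miR-3 seed tests with their 8mer, 6mer and coding alternatives were not run. Dim signal limits 163 called genes lower and 39 higher in mir-3 ectopic embryos, whose ratio is only a bound.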

Other observations

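The glycolysis list and the gene families below were chosen after the data were seen, and their tests are descriptions of these data. Of 13 measured genes, glycolytic enzymes and *Gpdh1*, in a list made once *Gapdh2* and *Tpi* were known to be far down, 9 fell and 3 rose, with a median of -0.27 (-0.32 to -0.26 under 6 other scalings). *Tpi* (-1.52), *Gapdh1* (-1.07), *Eno* (-0.60) and *PyK* (-0.40) fell with *Gapdh2*, while *Ald1* (0.32), *Hex-A* (0.32) and *Gpdh1* (0.28) rose. At least 1 of the 2 kept probes of *Tpi* missed the share of its ratio set above in the test for mismatched probes. The size of the *Tpi* ratio is thus not settled. The 2 kept probes of *Gapdh1* met that share, and *Gapdh2* had 1 kept probe. The camera p of 0.0041 (p = 0.13 with an estimated correlation) is not independent evidence, since some members had been seen.

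Over 116 families of genes sharing the start of their symbol, Tweedle genes fell in 12 of 14 with a median of -1.54, Cpr cuticle genes in 21 of 34 (-0.32) and Osiris genes in 11 of 15 (-0.51). Mitochondrial ribosomal proteins of the large subunit fell in 24 of 46 and rose in 7 (-0.15, camera adjusted p 0.045, but adjusted p = 0.93 with an estimated correlation). COP9 signalosome genes rose in 6 of 7 (0.25, camera adjusted p 0.027, but adjusted p = 0.93 with an estimated correlation). Proteasome beta subunits rose in 7 of 8 and fell in 1 (0.41, camera adjusted p 0.027, but adjusted p = 0.93 with an estimated correlation). The other proteasome families did not pass, with 5 of 8 alpha subunits higher and 2 lower (0.18, camera adjusted p 0.38), 5 of 9 Rpt genes lower and 2 higher (-0.27, camera adjusted p 0.53) and 7 of 14 Rpn genes lower and 1 higher (-0.15, camera adjusted p 0.12), and differences between these families were not tested. Under the 6 other scalings these medians kept their sign, but the cuticle families moved in size, from -3.21 to -1.49 for Tweedle, -1.02 to -0.30 for Cpr and -2.02 to -0.50 for Osiris genes. None of the families named here passed in camera with an estimated correlation (adjusted p = 0.93), a test with little power at 3 replicates.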
